A study of Pseudomonas putida KT2440 with 80 samples.

How the data were processed

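The data were 80 deposited samples from 40 arrays with 2 colours each. Every array was deposited once for its mutant and once for its wild-type channel, and both copies of each of the 40 scanner files were identical, so the measurements number 40. Per the labels, cultures of *Pseudomonas putida* KT2440 wild type and of 5 insertion mutants grew in minimal medium with 15 mM succinate at 30 °C, were brought to 10 °C and were harvested 2 h later. There were 2 cultures per mutant and 4 arrays per culture, with the dyes in both orientations.

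Per the file headers, spot intensities were extracted with Agilent Feature Extraction 10.5.1.1, which also wrote background-subtracted, dye-normalized intensities and their log10 ratio of red over green. Per its first line, the authors' table holds intensity values normalized by lowess within each array and left on a linear scale. The deposited series matrix equals log2 of that table after a shift of each column to a median of 8.77, and the authors' steps between them are otherwise not given in the sources used here. Each array held 11520 spots in 48 blocks under 5551 probe names: 5350 genes of this strain (5344 spotted 2 times, 4 spotted 1 time and 2 spotted 20 times), 200 other probes and 398 spots of a solvent control. Annotation came from the authors' table, in which 1354 genes have a symbol.

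The channel of the mutant was taken from the condition line of the authors' table. On 15 of 40 arrays this differs from the dyes in the labels; the scanner ratios follow the table on all arrays (smallest absolute correlation 0.998). In the series matrix, 28 columns follow the other channel of the table and 14 arrays run in the opposite direction, and on 1 array the dye line of the table opposes its values. Because the *aadA* probe, annotated as a streptomycin and spectinomycin resistance gene of a transposon, was higher in the mutant channel on 40 of 40 arrays, the condition line was kept. On 37 of these arrays that reading holds only with the probe names exchanged as described below. The labels name a gentamicin resistance element; whether that element carries a sequence like *aadA* could not be checked.

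Probe names were compared between 2 series of slides by the brightness of each block. In block rows 1 and 3, all 24 blocks of the 3 arrays of the first series (3 of the 4 arrays of *cbrA* culture 1) matched the neighbouring block of the other 37 arrays (median correlation 0.877, against 0.447 for the same block). In block rows 2 and 4, all 24 blocks matched their own (0.887). This concerns 2670 of 5350 genes (49.9%), of which 2640 stand exchanged with the next or previous locus number. On the 37 arrays, log ratios of neighbouring genes correlated at 0.200 with the names as deposited and at 0.347 with the names exchanged, where unaffected blocks had 0.337; on the 3 arrays the values were 0.251 as deposited and 0.161 exchanged. The *aadA* probe read 5.44 on the 3 arrays and 0.06 on the 37 under the deposited names, and the probe it exchanges with read 4.86 on the 37. These *aadA* readings take the direction from the condition line, so they and the check of direction by *aadA* are not independent. The brightness of the blocks does not use the direction. Names on the 37 arrays were therefore exchanged in these blocks, which was decided after the data were seen, and the deposited names were run as an alternative.

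Signals were background-corrected with normexp (offset 50) and normalized within arrays by loess in limma 3.58.1 under R 4.3.3; spots with a scanner outlier mark were left out, spots of a gene were averaged, and saturated spots were kept. A filter for genes well above background in at least 1 channel removed 0 genes. The arrays of a culture were averaged to 1 value with equal weight for both dye orientations, which left 10 values. These went into 1 limma fit with a mean per mutant (residual degrees of freedom 5, prior degrees of freedom 3.75), and genes with a Benjamini-Hochberg adjusted p below 0.05 were counted. The standard deviation over genes of the mean dye effect was 0.138 on the log2 scale, and the median SE of a mutant mean was 0.107. Contrasts in the same fit compared pairs of mutants and the mean of the 5 mutants with 0.

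Tested on simulated data with 5350 genes, the fit recovered 89.6% of genes changed 2-fold in *cbrA*, 94.0% in *cbrB*, 83.6% in *pcnB*, 97.0% in *vacB* and 95.5% in *bipA*. For 1.5-fold changes it recovered 53.7% in *cbrA*, 53.7% in *cbrB*, 53.7% in *pcnB*, 71.6% in *vacB* and 62.7% in *bipA*, and false calls made up 3.07% to 5.88%. The offset compresses ratios: a simulated log2 change of 2 was estimated at 1.62 to 1.87. The simulation changed 67, 67 and 66 genes per mutant by 1.5-, 2- and 4-fold, fewer than passed in the data. Its spread between cultures was that of the fit, which already holds array noise, and array noise was then added again. Cultures were drawn independently, and the rates hold for these settings only. Fitting the 40 arrays with culture as a random block gave 21.4% to 28.6% false calls on the same simulated data, so it served as an alternative only. Scan day was tested only as a term added to that fit, so its values differ by both choices.

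For 30 gene lists fixed before the data were examined, camera with a preset correlation between genes of 0.01 was run per mutant, adjusted over all 150 tests. Of these, 24 passed. With a correlation estimated from the data 0 passed in camera, with 9 at an unadjusted p below 0.05. Lists whose estimate lay under the preset value lost the call too, such as histidine utilisation in *vacB* (0.00536) and amino acid catabolism in *cbrA* (-0.01265). A higher correlation between genes is thus not what removed those calls. Rotation tests with fry, which do not compare a list with other genes, gave 46. Members were also counted after adjustment over the list alone. Correlations between mutants were set against 100 simulations of unchanged mutants that share the wild-type reading, since the labels do not say whether wild-type RNA was shared.

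Genes named in the text follow a rule set before the results: the 5 disrupted genes; members of their loci past the threshold; per mutant, the 10 largest rises and the 10 largest falls past the threshold with the same sign in both cultures and a symbol or known product; up to 4 members with the smallest adjusted p per list described; and, for contrasts, the 10 with the smallest p. Other named genes were chosen after their values were seen. PP1099 is not given as a fold, since its wild-type signal was saturated on all 8 arrays of *vacB* and of *bipA*. Alternatives covered background correction, normalization, source of values, weighting, filters, the fit, the test settings, scan day, and leaving out each culture. Gene tables with other identifiers could not be linked to these loci and were not used here.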

Results

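The soil bacterium *Pseudomonas putida* KT2440 and 5 of its transposon insertion mutants were compared in the cold. Per the labels, the insertions lie for 2 mutants in *cbrA* and *cbrB*, the sensor kinase and response regulator of a system that governs carbon and nitrogen use. Those of the other mutants lie in *pcnB*, which encodes poly(A) polymerase, in *vacB*, which encodes ribonuclease R, and in *bipA*, which encodes a ribosome-associated GTPase. Succinate-grown cultures were moved from 30 °C to 10 °C and harvested 2 h later. Each of 40 arrays carried 1 mutant and the wild type in opposite dyes, with 2 cultures per mutant and 4 arrays per culture, so n = 2 cultures for every mutant. The question was which genes differed between each mutant and wild type at 10 °C, and which of those differences were shared. All values are log2 of mutant over wild type, given with the standard error (SE) and the adjusted p of 1 fit over 5350 genes.

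Arrays of the same culture and dye orientation had a median correlation of log ratios of 0.90 (20 pairs, lowest 0.56), and arrays of the same culture in opposite orientations 0.571 (40 pairs, lowest 0.153). Between the 2 cultures of a mutant, means over arrays correlated at 0.67 for *cbrA*, 0.815 for *cbrB*, 0.685 for *pcnB*, 0.832 for *vacB* and 0.434 for *bipA*. Each culture was scanned on a single day and each of 5 days held 2 mutants, so the value of each culture is a within-day value. Medians given with scan day in the fit come from a fit of the 40 arrays with culture as a random block and scan day as a term. The probe of the resistance gene *aadA* read higher in the channel taken as the mutant on 40 of 40 arrays, by 3.22 to 6.61. This includes all 15 arrays where the labels and the authors' table name different dyes for the mutant. On 37 arrays it rests on the exchange of probe names described next. Under the deposited names *aadA* read -0.29 to 0.49 on those arrays, and the probe it exchanges with read 3.22 to 6.61.

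The probe names of 24 of 48 array blocks stand exchanged with those of the neighbouring block on 37 of the 40 arrays, relative to the other 3, and every gene name below follows the exchanged reading. Because no label says where a probe lies relative to its insertion, probes of the disrupted genes check nothing about the insertions. All 5 lie in exchanged blocks. The *cbrA* probe, PP4695, read 2.86 in the *cbrA* mutant (SE 0.13, n = 2 cultures, 2.56 and 3.17, adjusted p = 3.28e-05), and 0.56 with the names as deposited. It read -0.76 in the *cbrB* mutant (adjusted p = 0.003). The *cbrB* probe fell to -0.89 in its own mutant (SE 0.09, adjusted p = 0.000384), to -0.51 in *cbrA* and to -0.54 in *bipA*, and rose to 0.56 in *vacB*. The *pcnB* probe did not pass in its own mutant (-0.15, adjusted p = 0.389) and rose to 0.86 in *vacB* (adjusted p = 0.00098). The *vacB* probe read 0.09 in its own mutant (adjusted p = 0.758) and rose to 1.51 in *cbrB* and to 0.89 in *cbrA*. For *bipA* the reading was 0.24 in its own mutant (adjusted p = 0.273), with falls to -0.88 in *pcnB* and -1.1 in *vacB*. The deposited names turn some directions: the *bipA* probe then read -0.53 in its own mutant, 0.06 in *pcnB* and 0.28 in *vacB*, and the *cbrB* probe 1.79 in *cbrA*. Among neighbours of the insertions, *folK-2*, a folate synthesis gene next to *pcnB*, fell to -0.86 in *cbrB*, -0.44 in *cbrA* and -0.51 in *bipA* and rose to 0.55 in *vacB*. *panC*, for pantothenate synthesis, rose to 1.24 in *pcnB* and 0.71 in *vacB*, and PP4881, beside *vacB*, rose to 1.13 in *cbrB*.

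**Figure D1:**
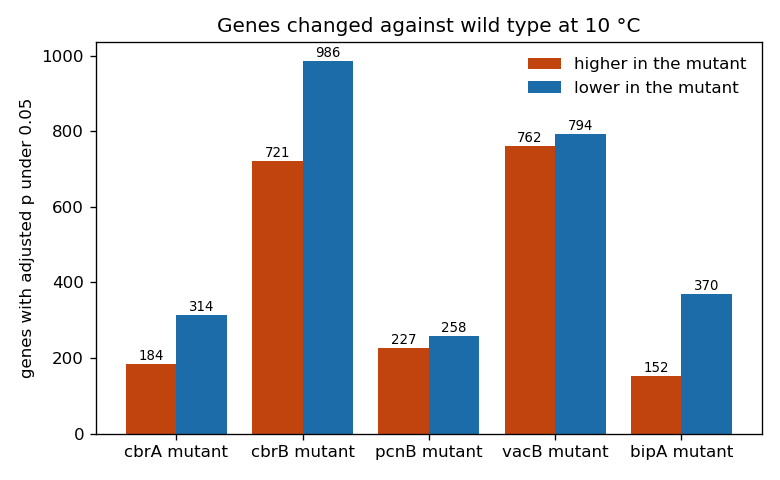
Genes higher and lower than wild type in each of the 5 mutants at 10 °C (limma, 2 cultures per mutant, 5350 genes).

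In the *cbrA* mutant, 8 of 34 genes for amino acid breakdown and several neighbours of PP2676 fell, and *pnp* and *vacB*, both for RNA-degrading enzymes, rose. PP2676, annotated as a periplasmic binding protein, fell to -2.64 (SE 0.35, n = 2 cultures, adjusted p = 0.00483). *aspA*, for aspartate ammonia-lyase, which releases ammonium from aspartate, fell to -1.67 (SE 0.09, adjusted p = 4.22e-05). *pnp*, for polynucleotide phosphorylase, an RNA-degrading enzyme needed in the cold by other bacteria, rose to 0.78 (SE 0.13, adjusted p = 0.00994). Past the threshold were 498 genes, 184 higher and 314 lower, of which 41 changed at least 2-fold, 8 higher and 33 lower.

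Near PP2676, the cytochrome gene PP2675 fell to -2.22, the aldehyde dehydrogenase gene PP2680 to -2.08 and PP2681, annotated for synthesis of the cofactor pyrroloquinoline quinone (PQQ), to -2.02. The regulator gene *agmR* fell to -1.81 and the sensor kinase gene PP2664 to -1.80. *ohr*, for a protein that detoxifies organic hydroperoxides, fell to -1.93 (SE 0.22, adjusted p = 0.00305). The branched-chain oxo acid dehydrogenase genes, which serve valine, leucine and isoleucine breakdown, fell together: *bkdA2* to -1.57 (SE 0.19, adjusted p = 0.00345), *bkdB* to -1.19, *bkdA1* to -1.07 and *lpdV* to -1.07. The alanine racemase gene *dadX* fell to -1.06 and the isocitrate lyase gene *aceA*, of the glyoxylate shunt, to -0.65. Rises included *betA*, for choline dehydrogenase in betaine synthesis, at 1.05 (SE 0.13, adjusted p = 0.00358), *vacB* at 0.89 (SE 0.18, adjusted p = 0.0242) and the ribosomal protein gene *rpmA* at 0.89 (SE 0.11, adjusted p = 0.00345). *nrdA*, for ribonucleotide reductase, rose to 0.86 (SE 0.21, adjusted p = 0.0417) and *infA*, for translation initiation factor IF-1, to 0.77 (SE 0.13, adjusted p = 0.0113). PP3095, an ATPase gene of the type VI secretion cluster, rose to 0.96 (adjusted p = 0.0468, and 0.0638 without the 3 arrays of the other slide series). *moaD*, for molybdopterin synthesis, rose to 0.90 (adjusted p = 0.0493, and 0.102 without them).

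Among gene lists in the *cbrA* mutant, the list of arginine, proline and other amino acid catabolism had 8 of 34 members lower, and 12 past the threshold (11 lower) adjusted over the list alone. Its median was -0.16, at -0.10 and -0.09 in the cultures and -0.19 with scan day in the fit (camera, adjusted p = 0.00204; adjusted p = 0.369 with an estimated correlation). Camera compares a list with the other genes, whereas the fry values below test whether its members moved one way on balance, which is another question. Members of the type VI secretion cluster, whose products form a contact-dependent injection apparatus, were higher in 5 of 13 cases, 7 adjusted over the list alone. The median was 0.58, at 0.50 and 0.47 in the cultures and 0.74 with scan day in the fit (adjusted p = 0.000238; adjusted p = 0.507 with an estimated correlation), and PP3088 rose to 1.08. Transposase genes, near-identical copies whose single readings are uncertain, were lower in 16 of 68 cases, 23 adjusted over the list alone. They had a median of -0.27, with cultures at -0.32 and -0.22 and -0.24 with scan day in the fit (adjusted p = 3.22e-09; adjusted p = 0.507 with an estimated correlation). Of 28 genes for fatty acid and membrane lipid synthesis, *fabB* (-1.07), *fabA* (-0.63) and *fabD* (-0.53) fell, and 3 passed adjusted over the list alone. The median was -0.10, at -0.24 and -0.04 in the cultures and -0.02 with scan day in the fit. That list had adjusted p = 0.0486, which became 0.225 without culture 1 of this mutant, 0.162 without the 3 arrays, 0.0597 with names as deposited and 0.0538 to 0.0597 without culture 2 of *pcnB*, culture 1 of *vacB* or culture 2 of *vacB*, and adjusted p = 0.539 with an estimated correlation; fry gave 0.0539. Prophage genes shifted up with a median of 0.10 (cultures 0.08 and 0.10, 0.05 with scan day in the fit; 11 of 200 higher, 5 lower, 5 adjusted over the list alone). Their adjusted p = 0.0127 became 0.0960 without culture 2 and 0.162 without the 3 arrays, and adjusted p = 0.623 with an estimated correlation; fry gave 0.101. For RNA degradation and processing, 3 of 15 genes rose, *pnp*, *vacB* and the ribonuclease P gene *rnpA* (0.56), *rnhA* fell to -0.44, and 6 passed adjusted over the list alone (adjusted p = 0.122; 0.0201 by fry).

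The *cbrA* count was 12 without culture 1 and 59 without culture 2, 306 with names as deposited, 256 with the arrays of this mutant alone and 95 with the channels fitted as separate samples (14.7% higher, against 36.95% here). Fitting the 40 arrays with culture as a random block gave 1264, and 947 with scan day added to that fit.

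In the *cbrB* mutant, *metK*, the oxidase genes *cioA* and *cioB* and *pnp* rose, and the *bkd* genes of branched-chain amino acid breakdown and the regulator genes *phoP* and *phoQ* fell. *metK*, for synthesis of S-adenosylmethionine, rose to 2.34 (SE 0.35, n = 2 cultures, 1.34 and 3.34, adjusted p = 0.00161). *cioA*, for a subunit of the cyanide-insensitive ubiquinol oxidase, rose to 2.00 (SE 0.15, adjusted p = 0.000105). *bkdA2* fell to -2.63 (SE 0.19, adjusted p = 8.84e-05) and *phoP*, for the response regulator that senses magnesium limitation with the kinase PhoQ, to -2.46 (SE 0.14, adjusted p = 4.96e-05). In all, 1707 genes passed, 721 higher and 986 lower, and 229 changed at least 2-fold, 64 higher and 165 lower.

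*cioB*, for the partner subunit, rose to 1.67 (SE 0.21). *pnp* rose to 1.77 (SE 0.13, adjusted p = 8.46e-05) and *metF*, for methylenetetrahydrofolate reductase, to 1.68 (SE 0.20). *cysNC*, for sulfate activation, rose to 1.56 (SE 0.14, adjusted p = 0.000183), *sucC*, for succinyl-CoA synthetase, to 1.53 (SE 0.38, adjusted p = 0.0157) and *vacB* to 1.51 (adjusted p = 0.000648). PP3781, annotated as an oxygen-independent coproporphyrinogen III oxidase, rose to 2.36 (cultures 1.46 and 3.26). Falls included *phoQ* at -2.37 (SE 0.16, adjusted p = 5.69e-05), PP1689, annotated as a long-chain fatty acid transporter, at -2.50 (SE 0.15, adjusted p = 4.96e-05), *ohr* at -2.23 (SE 0.22), *bkdB* at -2.05 (SE 0.16), *aspA* at -2.04 and *bkdA1* at -1.98. In the run around PP2676, which itself fell to -2.70, PP2675 fell to -2.37 and PP2680 to -2.18. *edd*, for phosphogluconate dehydratase of sugar breakdown, fell to -1.45. Of the glyceraldehyde phosphate dehydrogenase genes, *gap-1* fell to -1.11 and *gap-2* rose to 0.85. Of the protease genes, *lon-2* rose to 1.33, *clpP* to 1.16 (SE 0.08, adjusted p = 5.69e-05) and *clpX* to 0.95. The envelope stress sigma factor gene *algT* and its antagonist genes *mucA* and *algN* fell to -1.02, -1.15 and -1.18.

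Of the gene lists in the *cbrB* mutant, transposase genes were lower in 47 of 68 cases and higher in 1, and 53 passed (51 lower) adjusted over the list alone. Single readings of these near-identical copies are uncertain. The median was -0.51, at -0.48 and -0.53 in the cultures and -0.44 with scan day in the fit (adjusted p = 1.36e-11; adjusted p = 0.507 with an estimated correlation). The type VI secretion cluster was higher in 7 of 13 cases, 8 adjusted over the list alone, with PP3088 at 1.82 and PP3091 at 1.08. Its median was 0.73, at 0.60 and 0.76 in the cultures and 0.75 with scan day in the fit (adjusted p = 0.000411; adjusted p = 0.507 with an estimated correlation). Amino acid catabolism did not pass as a list in camera (adjusted p = 0.232; 0.000422 by fry) with 12 of 34 members lower, 6 higher and 19 past the threshold adjusted over the list alone; beside the *bkd* genes, *dadX* fell to -0.97. RNA degradation had 5 of 15 higher and 1 lower, 8 adjusted over the list alone (adjusted p = 0.0674; 0.00175 by fry). In the sulfur list, 8 of 33 rose and 1 fell, 9 adjusted over the list alone (adjusted p = 0.0771; 0.0013 by fry), with *cysD* at 1.31, *metY*, for homocysteine synthesis, at 0.91, and the regulator *cysB* at 0.68. Respiratory genes split, 13 higher and 10 lower of 46, 26 adjusted over the list alone (adjusted p = 0.859): beside *cioA* and *cioB*, the cytochrome o oxidase genes *cyoD* (-1.39) and *cyoC* (-0.90) and the NADH dehydrogenase gene *nuoA* (-1.15) fell. Flagellar and chemotaxis genes were lower in 14 of 64 cases, 14 adjusted over the list alone (adjusted p = 0.277), among them *fliC*, for flagellin, at -1.37, *flgM* at -1.12 and *cheR* at -1.05. Among translation factors, 5 of 22 rose and 2 fell, 7 adjusted over the list alone (adjusted p = 0.371), with *efp* at 1.28, *tsf* at 1.04 and *infA* at 0.90.

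The *cbrB* count was 948 without culture 1 and 667 without culture 2, and 590 with the channels fitted as separate samples. Fitting the 40 arrays with culture as a random block gave 2231, and 2106 with scan day added.

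In the *pcnB* mutant, *kdpA* and 11 of 46 respiratory chain genes rose, and *cspA-2*, *infA*, 10 of 53 ribosomal protein genes and several neighbours of PP2676 fell. *kdpA*, for the potassium-binding subunit of a high-affinity transporter, rose to 2.06 (SE 0.08, n = 2 cultures, adjusted p = 1.02e-05). *cspA-2*, for a cold shock protein, fell to -1.53 (SE 0.16, adjusted p = 0.00228), *rpmE*, for ribosomal protein L31, to -1.45 (SE 0.16, adjusted p = 0.00265) and *infA* to -1.36 (SE 0.13, adjusted p = 0.00228). Past the threshold were 485 genes, 227 higher and 258 lower, and 36 of them changed at least 2-fold, 5 higher and 31 lower.

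PP2676 fell to -2.74, PP2681 to -2.48, PP2680 to -2.40, PP2675 to -2.12, *agmR* to -1.97, PP2664 to -1.92, the hydrolase gene PP2678 to -1.54 and *qedH*, for a PQQ-dependent ethanol dehydrogenase, to -1.95 (SE 0.22, adjusted p = 0.00265). Further ribosomal protein genes lower were *rpsT* at -1.07 (SE 0.10), *rpmG* at -0.91 and *rpmB* at -0.77. The carbon storage regulator gene *csrA* fell to -0.66, *ohr* to -1.03, the glutamine synthetase gene *glnA* to -0.66 and *phhA*, for phenylalanine hydroxylase, to -0.65. Rises included *panC* at 1.24 (SE 0.14, adjusted p = 0.00265), *bioB*, for biotin synthase, at 1.04 (SE 0.27, adjusted p = 0.0448, and 0.0589 without the 3 arrays), *cyoB* at 0.94 (SE 0.11, adjusted p = 0.00265), *nuoN* at 0.94 (SE 0.14), *nouK* at 0.85 and *nuoL* at 0.85. None of the 3 arrays carried the *pcnB* mutant, so the adjusted p of *bioB* without them moved through the shared fit. The efflux channel gene *oprJ* rose to 0.74.

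Of the lists in the *pcnB* mutant, the type VI secretion cluster had 7 of 13 members higher, 10 adjusted over the list alone, with PP3098 at 1.06 and PP3091 at 0.99. The median was 0.66, at 0.63 and 0.60 in the cultures and 0.70 with scan day in the fit (adjusted p = 1.05e-05; adjusted p = 0.507 with an estimated correlation). Respiratory chain genes were higher in 11 of 46 cases and lower in 2, 16 (14 higher) adjusted over the list alone, with *cyoA* at 0.78, *cyoC* at 0.75 and *nuoH* at 0.60. Their median was 0.15, at 0.19 and 0.12 in the cultures and 0.09 with scan day in the fit (adjusted p = 0.0027; adjusted p = 0.569 with an estimated correlation). Ribosomal protein genes were lower in 10 of 53 cases and higher in 1, 17 (15 lower) adjusted over the list alone. They had a median of -0.16, at -0.10 and -0.31 in the cultures and -0.28 with scan day in the fit. Their adjusted p = 0.00439 became 0.242 with median centring, 0.0798 in the authors' table and 0.0734 without culture 2, and adjusted p = 0.623 with an estimated correlation; fry gave 0.069. Of 64 flagellar and chemotaxis genes 8 rose and 5 fell, 24 (19 higher) adjusted over the list alone. The median was 0.17, at 0.09 and 0.26 in the cultures and 0.06 with scan day in the fit. That adjusted p = 0.00895 became 0.296 without culture 2, 0.0549 without background correction and 0.0724 in the authors' table, and adjusted p = 0.736 with an estimated correlation; fry gave 0.292. In fatty acid and membrane lipid synthesis 4 of 28 rose, 5 adjusted over the list alone, with *fabB* at 0.56 and *lpxK*, for lipid A synthesis, at 0.52. The median was 0.15, at 0.15 and 0.12 in the cultures and 0.10 with scan day in the fit (adjusted p = 0.0118, and 0.0726 with names as deposited; adjusted p = 0.507 with an estimated correlation). Prophage genes were lower in 11 of 200 cases and higher in 1, 11 adjusted over the list alone. Here the median was -0.10, with -0.10 in both cultures and -0.11 with scan day in the fit (adjusted p = 0.000238; adjusted p = 0.532 with an estimated correlation). Of 15 cold shock and RNA chaperone genes 4 fell, 5 adjusted over the list alone (adjusted p = 0.0554; 0.0154 by fry).

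The *pcnB* count was 46 without culture 1 and 51 without culture 2, 273 without the 3 arrays, 81 with the channels as separate samples (28.4% higher), 1144 in the fit of 40 arrays with culture as a random block and 1105 with scan day added to it. Median centring gave 948 genes, 57.8% of them higher, against 46.8% here.

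In the *vacB* mutant, *infA*, *cspA-2* and 13 of 53 ribosomal protein genes fell, and 14 of 46 respiratory chain genes and 8 of 9 genes of histidine use rose. *infA* fell to -1.86 (SE 0.13, n = 2 cultures, adjusted p = 0.000263), *cspA-2* to -1.66 (SE 0.16, adjusted p = 0.000523) and *rpmE* to -1.58 (SE 0.16, adjusted p = 0.000651). *nuoN*, for a proton-pumping subunit, rose to 1.29 (SE 0.14), and *mrcB*, for a penicillin-binding protein, to 1.37 (SE 0.10, adjusted p = 0.000263). Past the threshold were 1556 genes, 762 higher and 794 lower, of which 111 changed at least 2-fold, 37 higher and 74 lower.

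*mltB*, for a murein-cleaving transglycosylase, rose to 1.44 (SE 0.11, adjusted p = 0.000364), *folP*, for folate synthesis, to 1.40 (SE 0.12), *lipB*, for lipoate attachment, to 1.23, *carB*, for carbamoyl phosphate synthesis, to 1.22 and *pstB*, for phosphate uptake, to 1.19. *pnp* rose to 0.93, the proline symporter gene *putP* to 0.98 and the membrane protease gene *ftsH* to 0.83. The run around PP2676 fell here too, PP2680 to -1.57 (cultures -2.22 and -0.93), PP2681 to -1.53, PP2676 to -1.46, *qedH* to -1.45 and PP2675 to -1.37. Further falls were *rpsT* at -1.30, *rpmG* at -1.18, *rpmB* at -1.0 and *csrA* at -0.83. Of 15 cold shock and RNA chaperone genes 6 fell and 3 rose, 9 adjusted over the list alone (adjusted p = 0.487).

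Genes of the stretch PP4600 to PP5049, 442 genes or 8.26% of those measured, had a median of 0.38 in the *vacB* mutant, 0.39 and 0.38 in the cultures, with 236 of the 762 higher calls inside it. The stretch was marked out after its values were seen; in the other mutants its median lay between -0.06 and 0.05. The *mltB*, *mrcB*, *folP*, *lipB*, *carB*, *pnp*, *putP*, *ftsH*, *psd*, *phaA* and *pilI* genes, the histidine genes and all 3 disrupted loci lie inside it, as does *fecA*, which fell; *nuoN* and *pstB* lie outside.

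**Figure D2:**
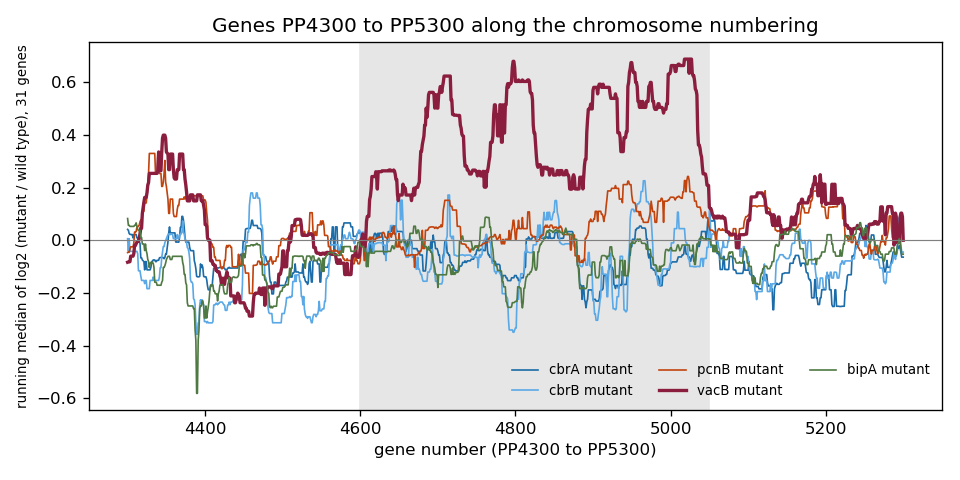
Running median of log2 mutant over wild type along the gene order from PP4300 to PP5300 in the 5 mutants; shading marks PP4600 to PP5049.

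Histidine utilisation had 8 of 9 genes higher in the *vacB* mutant, 8 adjusted over the list alone, with *hutU* at 0.84 and *hutI* at 0.74. Its median was 0.57, at 0.54 and 0.56 in the cultures and 0.50 with scan day in the fit (adjusted p = 0.000238; adjusted p = 0.369 with an estimated correlation). The *cbrA* locus with its neighbours, in the same stretch, had 7 of 9 higher, 8 adjusted over the list alone. Its median was 0.56, with cultures at 0.57 and 0.53 and 0.61 with scan day in the fit (adjusted p = 0.000343; adjusted p = 0.369 with an estimated correlation). Respiratory genes were higher in 14 of 46 cases and lower in 4, 23 (19 higher) adjusted over the list alone, with *nouK* at 1.18, *nuoJ* at 1.1 and *cyoB* at 0.88. The median was 0.21, at 0.24 and 0.20 in the cultures and 0.24 with scan day in the fit (adjusted p = 0.00326; adjusted p = 0.569 with an estimated correlation). Prophage genes were lower in 52 of 200 cases and higher in 4, 55 (51 lower) adjusted over the list alone. Here the median was -0.16, with cultures at -0.13 and -0.22 and -0.15 with scan day in the fit (adjusted p = 1.63e-06; adjusted p = 0.507 with an estimated correlation). Ribosomal protein genes were lower in 13 of 53 cases and higher in 2, 15 adjusted over the list alone. The median of these was -0.18, with cultures at -0.07 and -0.25 and -0.28 with scan day in the fit. Their adjusted p = 0.0168 became 0.149 without culture 2 and 0.0597 with names as deposited, and adjusted p = 0.657 with an estimated correlation; fry gave 0.0511. Flagellar and chemotaxis genes were higher in 25 of 64 cases and lower in 7, 39 (30 higher) adjusted over the list alone, with *flhF*, which places the flagellum, at 0.84, *fliF* at 0.67 and *fliJ* at -0.80. Their median was 0.26, at 0.40 and 0.17 in the cultures and 0.30 with scan day in the fit. The adjusted p = 0.0118 became 0.594 without culture 1, and adjusted p = 0.736 with an estimated correlation; fry gave 0.19.

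Fatty acid and membrane lipid genes were higher in 8 of 28 cases and lower in 1 in the *vacB* mutant, 10 (9 higher) adjusted over the list alone, with *lpxK* at 0.86, *fabB* at 0.74 and *psd*, for phosphatidylethanolamine synthesis and inside the stretch, at 0.58. The median was 0.19, at 0.19 in both cultures and 0.14 with scan day in the fit (adjusted p = 0.0118, and 0.0617 with names as deposited; adjusted p = 0.507 with an estimated correlation). In the list of polyhydroxyalkanoate metabolism 8 of 15 fell and 1 rose, 9 adjusted over the list alone. Several of the lower members serve phenylacetate breakdown and not the storage polymer, such as *phaB* (-1.03) and *phaE* (-0.66); *phaG* (-0.95) and *phaJ1* (-0.66) feed polymer synthesis, and the polymerase gene *phaA*, inside the stretch, rose to 0.66. The median was -0.32, at -0.22 and -0.43 in the cultures and -0.33 with scan day in the fit. The adjusted p = 0.0268 became 0.0613 without culture 2 and 0.185 with names as deposited, and adjusted p = 0.569 with an estimated correlation. Of 49 iron uptake genes 11 fell, 11 adjusted over the list alone, with the ferric citrate receptor gene *fecA* at -0.91, the siderophore receptor genes PP4137 and PP3330 at -0.89 and -0.88 and PP4243, for pyoverdine synthesis, at -0.84. The median was -0.12, at -0.09 and -0.11 in the cultures and -0.18 with scan day in the fit. The adjusted p = 0.0486 became 0.0723 without culture 2, 0.0655 without culture 1 or culture 2 of *cbrA*, 0.0511 without culture 2 of *bipA*, 0.0524 without background correction, 0.0582 in the authors' table and 0.141 with names as deposited, and adjusted p = 0.736 with an estimated correlation; fry gave 0.226.

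The *vacB* count was 440 without culture 1, 370 without culture 2 (58.9% higher, against 48.97% here) and 355 with the channels fitted as separate samples (61.7% higher). In the fit of 40 arrays with culture as a random block it was 2036, and 1834 with scan day added.

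In the *bipA* mutant, *efp* and 8 of 53 ribosomal protein genes rose, and PP2676 with several neighbours, 3 of 6 *pqq* genes and 12 of 64 flagellar and chemotaxis genes fell. *efp*, whose product helps ribosomes past proline stretches, rose to 1.01 (SE 0.12, n = 2 cultures, adjusted p = 0.00309), *rpmB*, for ribosomal protein L28, to 0.91 (SE 0.12, adjusted p = 0.00436) and *rpmG*, for L33, to 0.90. PP2676 fell to -2.46 and PP2664 to -1.91 (SE 0.20, adjusted p = 0.00178), and *pqqC*, for the last step of PQQ synthesis, to -1.22 (SE 0.13, adjusted p = 0.00233). Past the threshold were 522 genes, 152 higher and 370 lower, of which 39 changed at least 2-fold, 7 higher and 32 lower.

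PP1249, annotated as a lipoprotein, rose to 1.65 (SE 0.13, adjusted p = 0.000575) and *vanB*, for vanillate demethylation, to 1.20 (SE 0.16, adjusted p = 0.00446). PP3455 rose to 1.02 (SE 0.09, adjusted p = 0.000805) and its neighbour PP3456, both of an efflux system, to 0.92, and PP4547, annotated as a glutamine synthetase, to 1.01 (SE 0.12, adjusted p = 0.0029). *rnpA* rose to 0.86, *gap-2* to 0.79, *rpsA* to 0.65 and *rpmH* to 0.60. Further falls were PP2675 at -1.93, PP2680 at -1.84, the efflux transporter gene PP4930 at -1.79 (SE 0.20), *agmR* at -1.51, PP2681 at -1.35 and *aer-1*, for an aerotaxis receptor, at -1.31. The branched-chain oxo acid genes *bkdB* (-0.99), *lpdV* (-0.93) and *bkdA2* (-0.92) fell, as did *aspA* (-0.84), the oxidase genes *cyoA* (-0.84) and *cyoD* (-0.83) and the citrate synthase gene *gltA* (-0.70). The regulator gene PP0276 fell to -1.30 but had adjusted p = 0.298 without the 3 arrays. None of the 3 carried the *bipA* mutant, so this adjusted p moved through the shared fit.

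Of the lists in the *bipA* mutant, flagellar and chemotaxis genes were lower in 12 of 64 cases and higher in 1, 21 (20 lower) adjusted over the list alone, with *cheR* at -0.81. Their median was -0.16, at -0.13 and -0.26 in the cultures and -0.05 with scan day in the fit. The adjusted p = 0.000238 became 0.227 without culture 2, and adjusted p = 0.727 with an estimated correlation; fry gave 0.166. Transposase genes, uncertain as single readings, were lower in 15 of 68 cases, 23 adjusted over the list alone. Their median was -0.24, with cultures at -0.28 and -0.13 and -0.25 with scan day in the fit (adjusted p = 7.4e-08; adjusted p = 0.507 with an estimated correlation). Ribosomal protein genes were higher in 8 of 53 cases and lower in 2, 16 (12 higher) adjusted over the list alone (adjusted p = 0.0771). In amino acid catabolism 6 of 34 fell, 8 adjusted over the list alone (adjusted p = 0.245; 0.0104 by fry).

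The *bipA* count, with 29.1% higher, was 74 without culture 1, 911 without culture 2 (47.7% higher), 280 without the 3 arrays, 46 with the arrays of this mutant alone (13.04%), 44 with the channels as separate samples, 253 with the scanner's own ratio (19.4%), 1234 in the fit of 40 arrays with culture as a random block (41.7%) and 1323 with scan day added (44.4%). Median centring put 16.5% higher, and with the labels' dyes 0 genes passed and 4 of the 522 kept their sign.

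CbrA and CbrB form a kinase and regulator pair, so the comparison of their mutants asked whether either changed genes that the other did not. Past the threshold were 13 genes between *cbrA* and *cbrB*, 8 higher and 5 lower in *cbrA*, with 751 at an unadjusted p below 0.05 in limma. The median SE of this contrast was 0.152, against 0.107 for a mutant mean, so the low count does not show the mutants to be alike. Apart from the *cbrA* probe (3.62, SE 0.19, adjusted p = 8.48e-05), *phoP* was higher in *cbrA* by 1.49 (SE 0.20, n = 2 cultures per mutant, adjusted p = 0.0272) and *cysNC* lower at -1.51 (SE 0.19, adjusted p = 0.0247). *cioA* was lower at -1.69 (SE 0.22, adjusted p = 0.0247), and passed neither without background correction nor in the authors' table. PP1689 was higher by 1.51 (SE 0.21, adjusted p = 0.0309), and had adjusted p = 0.0689 without the 3 arrays. *cyoC* (0.89, adjusted p = 0.0272) and *gap-2* (-0.85, adjusted p = 0.0297) were also lost under other processing. The count was 1 without culture 1 of *cbrA* and 104 without culture 1 of *cbrB*, 8 with the arrays of these mutants alone, 458 in the fit of 40 arrays with culture as a random block and 661 with scan day added to it. The share higher was 61.5% here, 41.2% of 17 genes with median centring, 46.2% of 13 with the scanner's own ratio, 35% of 20 with the channels as separate samples and 25% of the 104 and of the 8.

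In answer to the question of which responses were shared, changes correlated most among *cbrA*, *cbrB* and *bipA*, and between *pcnB* and *vacB*. Over genes that passed in either, the Pearson correlation was 0.824 for *cbrA* with *cbrB* (Spearman 0.83, 1802 genes), 0.685 for *cbrA* with *bipA* (0.644, 807 genes), 0.687 for *cbrB* with *bipA* (0.714, 1838 genes) and 0.883 for *pcnB* with *vacB* (0.89, 1613 genes). The other 6 pairs lay between -0.167 and 0.241 (Spearman -0.296 to 0.0944). A shared wild-type reading alone gave 0.501 over 100 simulated draws and a covariance of 0.00861, against covariances over all genes of 0.108, 0.0617, 0.0875 and 0.0981 for the 4 pairs. The covariances less the simulated one were 0.099, 0.0531, 0.0789 and 0.0894. The simulation gave mutant and wild-type readings equal variance, which by itself sets its correlation near 0.501. Its spread came from differences between cultures of a mutant, so a wild-type deviation common to all cultures is absent from it. It therefore sets no upper bound on the effect of shared controls. Without culture 1 of *bipA*, *cbrB* with *bipA* correlated at 0.473, and single cultures of *cbrB* with culture 2 of *bipA* at 0.458 and 0.467. The simulated 0.501 holds for means of 2 cultures over all genes, so these values cannot be set against it. In *cbrA* and *cbrB* 115 genes were higher in both, where 24.8 would overlap by their numbers, and 287 lower in both, where 57.9 would. For *cbrA* with *bipA* these were 50 (5.23) and 157 (21.7), for *cbrB* with *bipA* 88 (20.5) and 294 (68.2), and for *pcnB* with *vacB* 186 (32.3) and 242 (38.3). In the other 6 pairs, too, more genes were lower in both than their numbers give. These were 68 (17.8) for *pcnB* with *bipA*, 131 (54.9) for *vacB* with *bipA* and 179 (146) for *cbrB* with *vacB*, among others. Genes higher in both showed no such excess in *cbrA* with *vacB* (13, against 26.2) or *vacB* with *bipA* (21, against 21.7). Part of the excess of these overlaps may come from the shared controls.

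Direct comparisons named the genes that set the mutants apart. *aspA* was lower in *cbrA* than in *pcnB* (-1.72) and *vacB* (-2.08), and lower in *cbrB* than in *pcnB* (-2.09) and *vacB* (-2.45). *infA* was higher in *cbrA* than in *pcnB* (2.14) and *vacB* (2.64), and in *cbrB* than in *vacB* (2.77). Between *pcnB* and *vacB* only *kdpA* passed, higher in *pcnB* by 1.38 (SE 0.12, n = 2 cultures per mutant, adjusted p = 0.00601), with adjusted p = 0.343 without background correction and 0.686 in the authors' table. Of the 100 genes with the smallest p in this contrast, 87 lie in the stretch PP4600 to PP5049, which had a median difference of -0.36, against 0.02 for the other genes. *rpmB* was lower in *pcnB* than in *bipA* (-1.69) and in *vacB* than in *bipA* (-1.91), and *cyoB* was higher in *pcnB* than in *bipA* (1.52). PP4547 was lower in *cbrA* (-2.25) and in *cbrB* (-2.17) than in *bipA*, and *cioA* was higher in *cbrB* than in *bipA* by 2.36, with *phoP* lower (-2.14). The numbers of genes past the threshold were 807 for *cbrA* against *pcnB*, 1510 for *cbrA* against *vacB*, 18 for *cbrA* against *bipA* and 1549 for *cbrB* against *pcnB*. They were 2006 for *cbrB* against *vacB*, 143 for *cbrB* against *bipA*, 485 for *pcnB* against *bipA* and 1245 for *vacB* against *bipA*.

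The mean of the 5 mutants was compared with wild type, which does not show a change in each. Its SE takes the 10 values as independent, although wild-type RNA may have been shared. The mean differed from wild type for 1944 genes, 931 higher and 1013 lower, and all 17 that differed at least 2-fold were lower. PP2664 was lower at -1.75 (SE 0.09, n = 2 cultures for each of 5 mutants, adjusted p = 8.07e-06), *agmR* at -1.52, PP2680 at -2.02, *pqqC* at -1.12 (SE 0.06, adjusted p = 1.03e-05) and *pqqA*, for the peptide precursor of PQQ, at -0.88. *clpP*, for a protease, was higher by 0.55 (SE 0.03, adjusted p = 1.97e-05). The mean of *aspA* was -0.81, but *aspA* was higher in *vacB* (0.41). The count lay between 1417 and 2071 when a culture was left out, and was 222 with the channels fitted as separate samples (14.4% higher, against 47.9% here); fits of the 40 arrays put 50.2% to 54.2% higher.

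**Figure D3:**
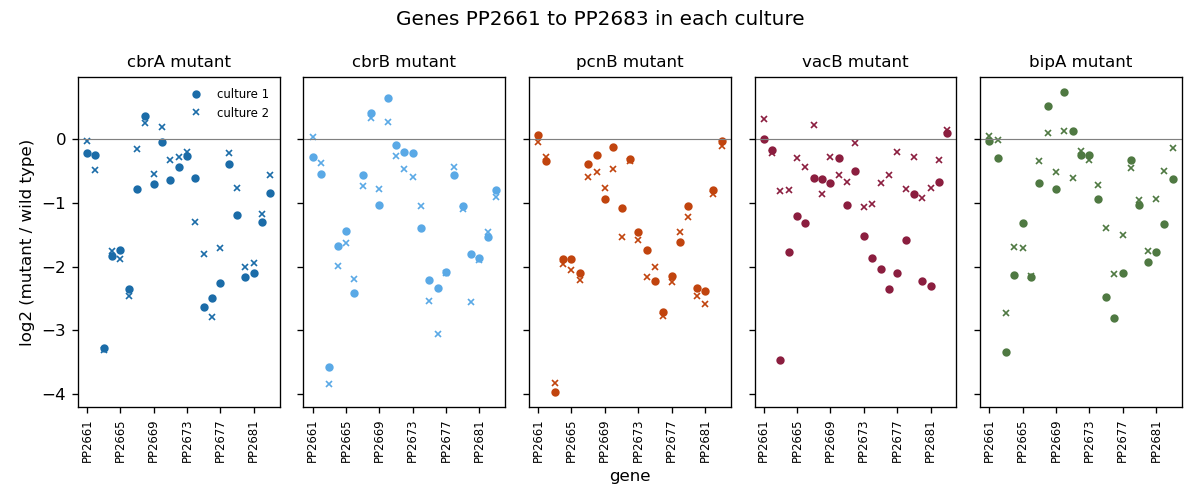
Log2 of mutant over wild type for genes PP2661 to PP2683 in the 5 mutants; dots are culture 1 and crosses culture 2.

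Genes PP2661 to PP2683, grouped after their values were seen, were lower in 14 of 23 cases in *cbrA*, 18 in *cbrB* (with 1 higher), 16 in *pcnB*, 16 in *vacB* and 13 in *bipA*. Their medians were -0.96, -1.08, -1.52, -0.86 and -0.84, and in *vacB* the cultures read -1.21 and -0.56. PP2679, a second PQQ-dependent ethanol dehydrogenase gene, fell to between -1.14 (*pcnB*) and -0.58 (*vacB*). The sensor kinase gene PP2671 fell in *pcnB* (-1.31) and *vacB* (-0.86), and PP2683, another sensor kinase gene, in *cbrA* (-0.70) and *cbrB* (-0.85). Of 6 *pqq* genes elsewhere on the chromosome, 4 fell in *cbrA*, 4 in *cbrB*, 4 in *pcnB*, 2 in *vacB* and 3 in *bipA*.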

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

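Of the tests below, the one on scan day was chosen only after the result was seen.

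Some arrays lay apart from the other 7 of their mutant. Array 1 of *cbrB* culture 1 had 2.44% of gene spots marked as outliers by the scanner, and array 2 of *bipA* culture 1 had 1.39%. Arrays 2 and 3 of *pcnB* culture 2 had more, 10.25% and 7.87%, but as a pair neither stood alone. The brightness of array 2 of *pcnB* culture 2 correlated at 0.859 with the median array, and that of array 2 of *vacB* culture 1 at 0.94. On array 3 of *vacB* culture 1 the *aadA* probe read 3.22, the lowest of the 40 arrays. These were 5 of 20 such comparisons, where chance alone singles out about 1 in 20.

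Among probes outside the genes of this strain, the *aadA* probe had a mean log2 of 4.90 over the 40 arrays, higher in the mutant channel on each. Probes of *arpB* and *ttgB* from another strain also read higher on all 40 arrays, at means of 0.63 and 0.65; of 200 such probes these 3 did so.

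Direct contrasts between mutants found 13 genes between *cbrA* and *cbrB*, 18 between *cbrA* and *bipA*, 143 between *cbrB* and *bipA* and 1 between *pcnB* and *vacB*; across these sets there were 807 between *cbrA* and *pcnB*, 1510 between *cbrA* and *vacB*, 1549 between *cbrB* and *pcnB*, 2006 between *cbrB* and *vacB*, 485 between *pcnB* and *bipA* and 1245 between *vacB* and *bipA*. Different wild-type RNA on the arrays of each set would put the difference in the wild-type channel, but that channel carried -6.57% of it, and -10.5% to -3.06% with a culture left out. Scan day would make cultures of different sets scanned together alike. The higher correlation of the 2 such pairs was 0.208, and the lowest among 13 pairs of 1 set on different days was 0.277, both with culture 2 of *bipA*. The sets were drawn from the likeness of these same values, so this comparison cannot exclude scan day. Day went with likeness: pairs of 1 day averaged 0.686 against 0.582 within sets and 0.0822 against -0.0269 between sets. Another culture batch or harvest point of the *pcnB* and *vacB* cultures stays open, as does a biological difference between the sets; neither was tested.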

How the results depend on the processing

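Tests with deposited probe names, without the 3 arrays of the other slide series, with the labels' dyes and with the 25 arrays on which both dye sources agree were chosen after the data were seen. Values below are numbers of genes, in the order *cbrA*, *cbrB*, *pcnB*, *vacB*, *bipA*, then the contrast of *cbrA* with *cbrB* and the mean of the 5 mutants, where each moved by over 1.5 times; unless stated, the cause was not tested.

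Fits that treat arrays as the units have more degrees of freedom by construction: as if independent, 2407, 3222, 2199, 2981, 2318, 1256 and 3278. With culture as a random block the numbers were 1264 (*cbrA*), 1144 (*pcnB*), 1234 (*bipA*) and 458 (contrast), and with scan day added 947, 1105, 1323 and 661; *cbrB* and *vacB* stayed within 1.5 times. With the channels fitted as separate samples (no replicate block, without the pairing by array), 95, 590, 81, 355, 44, 20 and 222. With the arrays of the mutants compared alone, 256 (*cbrA*), 46 (*bipA*) and 8 (contrast). Asking for a 2-fold change as well, which removes genes by construction, left 41, 229, 36, 111, 39 and, for the mean, 17.

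Culture deviations of the mutants went together in part: over 10 pairs of mutants their correlations were all positive, between 0.0625 and 0.47. They were not all over 0.1, and the main fit held no block for the culture number. A replicate block for the culture number gave 1024 (*cbrA*), 877 (*pcnB*), 910 (*bipA*) and 53 (contrast).

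With the labels' dyes for the direction, 0 genes passed in limma for every mutant, the contrast and the mean, with 172, 458, 84, 105, 21, 57 and 102 at an unadjusted p below 0.05; ratios of opposite sign are then averaged by construction. Of the 522 *bipA* calls 4 then kept their sign, so its directions turned as a whole, against 497 of 498 kept in *cbrA*, 1706 of 1707 in *cbrB*, 475 of 485 in *pcnB* and 1549 of 1556 in *vacB*. With the 25 arrays alone, the counts of all mutants, the contrast and the mean stayed within 1.5 times. Deposited names gave 306 for *cbrA*, whose arrays then mix different genes by construction. Without the 3 arrays, *pcnB* had 273, *bipA* 280 and the contrast 8. The 3 arrays are of *cbrA*, so the counts of *pcnB* and *bipA* moved through the shared fit. For *bipA* there were 332 genes without background correction, 253 with the scanner's own ratio and 254 in the authors' table. Median centring gave 948 for *pcnB*, and eBayes with trend and robust settings 7 for the contrast. Scaling of brightness between arrays and the filter on dim genes altered no ratio or gene, so both were void.

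Leaving out a culture gave 12 to 59 for *cbrA*, 667 to 948 for *cbrB*, 46 to 51 for *pcnB*, 370 to 440 for *vacB*, 74 to 911 for *bipA*, 1 to 104 for the contrast and 1417 to 2071 for the mean; the lone culture left is assumed to vary like the others. The share of higher calls without culture 2 was 47.7% in *bipA*, 31.3% in *cbrB* and 58.9% in *vacB*, where it was 61.7% with separate channels, against 48.97%. List calls numbered 21 to 31 with a culture left out, 37 with median centring, 46 with fry (16 of them among the 24) and 0 with an estimated correlation in camera (9 at an unadjusted p below 0.05), against 24.

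Correlations moved less. That of *cbrA* with *cbrB* was 0.763 without the 3 arrays, 0.779 between different culture numbers, 0.760 over all genes and 0.776 to 0.840 with a culture left out. For *pcnB* with *vacB* it was 0.820 between different culture numbers, 0.833 over all genes and 0.836 to 0.893 with a culture left out. Leaving out a culture gave 0.580 to 0.723 for *cbrA* with *bipA* and 0.473 to 0.748 for *cbrB* with *bipA*. That of *cbrA* with *pcnB*, 0.0781, reversed to -0.0435 over all genes, was 0.0393 with median centring and 0.101 without the 3 arrays; *cbrA* with *vacB* was -0.0992 without them, and *pcnB* with *bipA* 0.108 over all genes. Over all settings *cbrB* with *pcnB* (0.0563) spanned -0.0546 to 0.154, *cbrB* with *vacB* (-0.0597) -0.149 to 0.00449 and *vacB* with *bipA* (0.0191) -0.120 to 0.198.

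Of the single genes chosen by the rule, *ntrB* in *vacB* (0.32) reversed to -0.0616 without background correction and -0.0232 in the authors' table. With median centring 140 kept their direction and side of the threshold, 3 lost the call and 3 gained it; without the 3 arrays 135 did, 9 lost it and 2 gained it. Without background correction 143 did, and 142 with the values of the authors. Leaving out a culture ended most calls in *cbrA* (18 of them without culture 1, 17 without culture 2), and 13 and 3 in *bipA*, 10 and 14 in *pcnB*, 12 and 11 in *vacB* and 2 and 6 in *cbrB*.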

Other observations

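Of the tests below, those on the edges of the stretch and on windows of genes were chosen only after the result was seen.

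*ttgA*, of a solvent and antibiotic pump, rose in *cbrB* (0.59), *pcnB* (0.36), *vacB* (0.63) and *bipA* (0.48), and its repressor gene *ttgR* rose in *cbrA* (0.54), *cbrB* (0.59) and *vacB* (0.75). Of 12 multidrug efflux genes, 1 rose in *cbrA*, 4 in *cbrB*, 3 in *pcnB* and 2 in *bipA*, and in *vacB* 4 rose and 2 fell. As a list they passed in none of the 5 mutants in camera (adjusted p 0.101 to 0.612). By fry the adjusted p was 0.0361 in *cbrB*, 0.0367 in *vacB*, 0.0503 in *pcnB*, 0.0574 in *bipA* and 0.288 in *cbrA*. Among type IV pilus genes, *pilI*, for a signalling protein, fell in *cbrA* (-0.46), *cbrB* (-0.60) and *bipA* (-0.42) and rose in *pcnB* (0.32) and *vacB* (0.88); it lies in the stretch PP4600 to PP5049, which read higher in *vacB*. Of the cold shock genes, PP1209 fell in *cbrA* (-0.47), *cbrB* (-0.49), *pcnB* (-0.56), *vacB* (-0.70) and *bipA* (-0.50), and *cspA-2* fell in *pcnB* and *vacB* and rose in *cbrB* (0.48).

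The stretch PP4600 to PP5049 had a higher median than the other genes in the *vacB* mutant, on each of its 8 arrays (differences of medians 0.247 to 0.593). On the other 32 arrays the differences were -0.316 to 0.22. Placement of the spots within a block would raise other genes at the same positions within blocks, but the higher median of 998 such genes over the cultures was -0.0090. Placement by block or region of the slide was not tested. Over 4 other ways of processing the stretch stood above the other genes by at least 0.380. Copies of the element ISPpu10 lie at PP4599 and PP5050, and an edge of the best-scoring stretch, PP4676 to PP5043 (360 genes, median 0.44), lay 77 genes away. The 76 genes before it also read higher (median 0.20, with 0.15 and 0.21 in the cultures). Of 4833 windows of 76 genes outside, which overlap and so are not independent, 0.931% reached that median, the highest at 0.257. Every window of 76 genes within the best-scoring stretch lay above the median of 0.20, the lowest at 0.248. That stretch was picked for its high score on these same values, which favours this outcome, so nothing is drawn from it. The last 6 genes, PP5044 to PP5049, read -0.09 in *vacB*. They read -0.34 in *pcnB*, whose changes were most like those of *vacB*, and 0.12, 0.22 and 0.06 in *cbrA*, *cbrB* and *bipA*. A duplication between the copies would put the edge nearer to them, but the 76 genes before it also read higher. The distance of the edge thus cannot decide on such a duplication. Extra copies of every gene would lift weak and strong responders alike. The lower quartile rose by 0.925 of the rise of the median at the lower culture. The upper quartile rose more than the median, by 0.497 and 0.501 in the cultures against 0.4005 and 0.3985. Any shift of the whole stretch would lift the lower quartile too, so the quartiles cannot tell a duplication from another rise of the stretch. A duplication stays a candidate explanation, though a simulated 2-fold change was estimated at 0.89.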
